A study of Caenorhabditis elegans with 4 samples.

How the data were processed

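RNA from 4 preparations of wild-type adult Caenorhabditis elegans, a nematode worm, was compared with one wild-type mixed reference RNA on 4 two-colour microarrays. The labels number the adult preparations (preps) 1 to 4, place the adult RNA in channel 2 and the reference RNA in channel 1 of every array, and do not say what was mixed in the reference. All 4 arrays form 1 group, so the comparison that the design allows is the ratio of adult RNA against the reference. A test against a common reference leaves out the reference's own spread. No array had the channels swapped, so a gene's channel or dye effect cannot be told apart from a difference between adults and reference.

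The deposited table holds 1 log2 ratio per probe and array. The unit was taken from the values, since raising 2 to the deposited log2 value gave a ratio with 3 decimals (within 0.00001) for 99.934% to 99.995% of the spots of each array. The authors' scanner, dyes, background correction, spot filter and normalization method are not given in the sources used here. The array medians of the deposited log2 ratios lay between -0.0043 and 0.0496, and whether the authors centred the arrays is not given in the sources used here. The numerator of the ratio is not stated either. The direction of adult over reference is called likely here, because the adult RNA is in channel 2 and tables of this kind usually give channel 2 over channel 1. The vitellogenins, which are made in adults and were fixed in advance, do not settle it, as vit-2, vit-5 and vit-6 had means of -0.27, 0.03 and 0.88. Of other lists fixed in advance, the sperm and oocyte genes had positive medians and the moulting genes negative medians on every array. What was mixed in the reference is not stated, so these lists were not used to set the direction. Positive values are read below as likely higher in adults, and the sign of every array was used as deposited. The lowest correlation between 2 arrays over all probes was 0.659, so no array ran against the others.

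The table has 21632 probes, of which 20937 had a value on all 4 arrays. GEO's platform annotation gave 1 gene symbol for 16450 probes, several for 247 and none for 4935. Of the probes with 1 symbol, 16360 were matched by gene ID and 5 by accession to the RefSeq genes of assembly WBcel235, while 85 kept the annotation's symbol. That table was used for symbols and for the chromosome of each gene, and no coordinates are given because no build is named for the arrays. Probes of 1 gene were averaged on each array, which gave 14943 genes, 1456 of them with several probes. The median range between probes of one gene was 0.258 on the log2 scale, and for 27 genes the probes lay above 0.5 and below -0.5. Probes with several genes or none were left out of the gene tests.

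Genes with a value on at least 3 arrays were fitted with limma 3.58.1 in R 4.3.3 (an intercept, lmFit and eBayes), two-sided against a log2 ratio of 0, with Benjamini-Hochberg adjustment over 14935 genes and a threshold of 0.05. The labels name separate preparations but do not say whether each came from its own culture, so p-values measure the spread between these preparations. Means are given with the SD over the 4 arrays, and the number of arrays limits the precision. Without signal intensities it is unknown which spots were close to background, where a ratio is drawn towards 0.

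A total of 24 gene lists was fixed before the data were examined, together with the tests, the rule for named genes and most alternatives. The lists cover the germline, sperm, embryo, cuticle, tissues, housekeeping complexes and large gene families. Each was compared with all other genes by camera with a preset correlation between genes of 0.01, two-sided, on genes with values on all 4 arrays, and adjusted over the lists. The same test with an estimated correlation, which has 3 residual degrees of freedom, and fry, which tests a list by itself, were run beside it. The refits under other settings used cameraPR, a form of camera that takes the gene statistics of each fit, with the same preset correlation. A small change in a list's adjusted p under those settings can therefore also come from the change of procedure. Calls on the X chromosome and on the autosomes were compared with Fisher's exact test. The text names the 6 genes with the largest positive and the 6 with the largest negative mean among called genes of one sign on all 4 arrays, the 2 members of each list with the largest mean in size, and every vitellogenin with a probe of its own. Probes on such arrays may bind near-identical family members, so the msp, vit, col, his, ugt and cyp values are uncertain for single genes.

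The tests were tried on simulated data with the real genes' spread and missing values. With 200 of 14935 genes changed, limma recovered 0% of the genes changed by 0.5, 54% of those changed by 1, 88% of those changed by 2 and 96% of those changed by 3 on the log2 scale, with 3 false calls among 122. In the real data 44.5% of the genes were called. The adjustment depends on that share, so these recovery rates do not carry over to the real data. Of 200 unshifted simulated lists, camera called 2.5%. The simulated genes were drawn independently of one another, so this share does not check camera on lists of correlated genes. The estimated correlation in the real lists reached 0.804, in the major sperm proteins.

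The alternatives were centring and scaling of the arrays, other minimum numbers of arrays, a robust prior, array weights, leaving out each prep, a minimum size of change, and single probes in place of gene means. The titles date preps 1 and 2 to consecutive days, and these arrays were kept as separate blocks. Preps 3 and 4 have the same date in the month before. That date was used as a random block, and preps 3 and 4 were also fitted alone. In that fit of 2 arrays limma gave every gene the same standard error (0.262), so its p-values leave out the gene's own spread. limma's usual estimate of the block correlation gave no value for 4 arrays in 3 blocks, and a correlation of 0.2714, taken from the differences between arrays, was used after seeing the data. Tests of explanations used Python 3.11.15 with scipy 1.17.1.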

Results

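Gene expression in wild-type adult worms was measured against a mixed reference RNA on 4 two-colour arrays, 1 for each adult preparation. Between 21243 and 21501 of the 21632 probes had a log2 ratio on each array, and the SD of the ratios was 0.921 on prep 1, 0.859 on prep 2, 0.756 on prep 3 and 0.836 on prep 4. The arrays correlated with one another over the probes with Pearson's r between 0.659, for preps 1 and 4, and 0.755, for preps 3 and 4, which share a date in their titles. Probes are not independent replicates. The SD of the difference between 2 arrays ranged from 0.561 to 0.729, so no array was a copy of another. Positive ratios likely stand for higher RNA levels in the adults relative to other genes, and each value is given with its SD over n = 4 preps. The ratios do not tell a change within a tissue from a change in that tissue's share of the RNA.

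The first comparison asked which genes differed between adults and the mixed reference. As lists, sperm, oocyte, germline and cell division genes had positive ratios, and moulting, hedgehog-related, neuronal and neuropeptide genes had negative ones, in a test with a preset correlation between genes. No list was called with an estimated correlation. The largest positive mean was that of irg-5, an infection response gene, at 4.98 ± 0.38 (31.7-fold). The pud family, named for proteins abundant in insulin receptor mutants, followed, as pud-2.1 had 4.29 ± 0.65 and pud-4 had 3.90 ± 0.33. The glucuronosyltransferase genes ugt-13 and ugt-63, of a family of detoxification enzymes, had 3.94 ± 1.26 and 3.93 ± 0.38, and the collagen gene col-129 had 3.76 ± 0.58. At the other end stood 4 genes of the collagen list: col-36 at -4.79 ± 0.91 (27.6-fold lower), col-84 at -4.24 ± 0.63, col-158 at -4.08 ± 0.36 and rol-8 at -4.03 ± 0.22. They were joined by ora-1 at -4.41 ± 0.46 and by hsp-12.6, a small heat shock protein gene, at -3.92 ± 0.46. The adjusted p of these 12 genes in limma lay between 1.5e-05 and 2.1e-04. The same sign on all 4 arrays was part of the rule that picked them.

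Of 14935 genes tested, limma called 6639 (44.5%) at an adjusted p under 0.05. The channels were never swapped, so these calls can include channel effects of single genes. Positive ratios made up 3468 of the calls and negative ratios 3171, a majority that turned when the arrays were centred on their medians (3114 against 3405) or also scaled (3155 against 3420). Of the 6639 called genes, 6402 had one sign on all 4 arrays. A mean log2 ratio of at least 1 in size was reached by 2132 called genes, of which 929 were positive and 1203 negative. The median over all genes tested was 0.064.

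**Figure D1:**
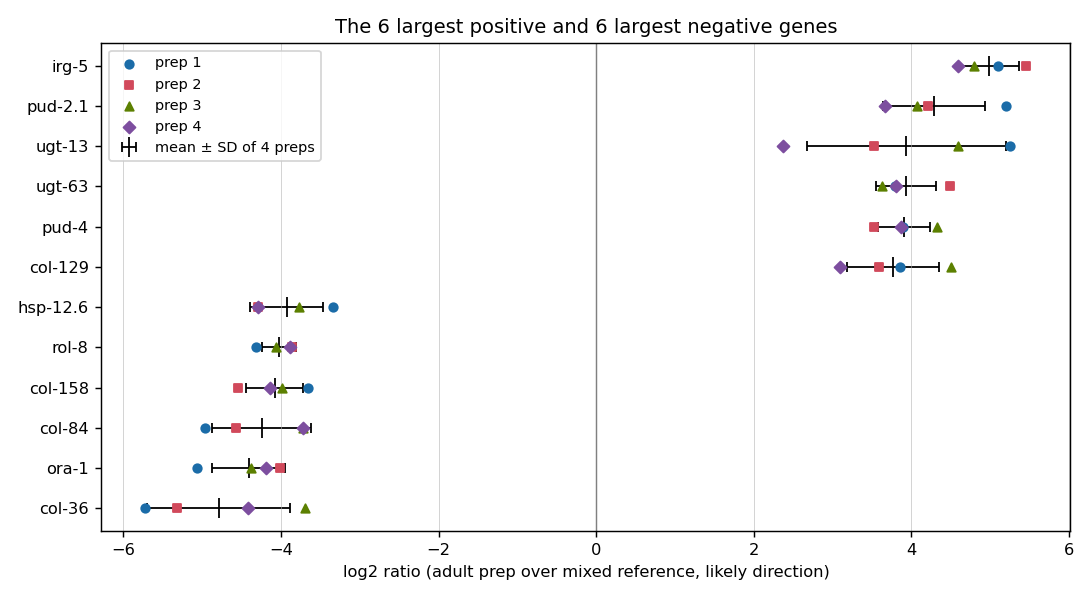
Log2 ratio of adult RNA over the mixed reference (horizontal axis, likely direction) on each of the 4 arrays for the 6 genes with the largest positive and the 6 with the largest negative mean. Symbols are single preps and bars are the mean ± SD. The genes were picked for large means and one sign on all 4 arrays, which favours a spread that is small beside the mean. The spread between preps is largest for ugt-13 (2.37 on prep 4 and 5.25 on prep 1).

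The second comparison asked which groups of genes moved together. Of the 24 lists, camera called 15, 8 with positive and 7 with negative ratios, and none kept its call with an estimated correlation, where 3 residual degrees of freedom remain. The estimated correlation was 0.804 for the major sperm proteins, 0.68 for the oocyte list and 0.579 for the germline list, but 0.029 for the neuropeptides. Where it lies far above the preset 0.01, camera's p-value with the preset correlation is likely too small. The list values below are medians of the mean ratios of the tested members of each list, followed by the SD of the 4 array medians. A median of means can lie outside the array medians, as it does for the neuropeptides. Members are counted as positive or negative only where limma called them. Of the genes measured on all arrays, limma called 23.4% positive and 21.4% negative.

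Sperm genes had the highest ratios of the lists. The major sperm proteins, the cytoskeletal and signalling proteins of nematode sperm, had a median of 2.53 (SD of the array medians 0.45), and 29 of 30 members were called positive, with none negative (camera adjusted p = 7.1e-17, adjusted p = 0.42 with an estimated correlation). The family members msp-10 at 3.00 ± 0.72 and msp-36 at 2.94 ± 0.42 are near-identical in sequence to others and may share signal. Of the other sperm genes, 23 of 30 were called positive and 7 were not called, with a median of 1.15 (SD 0.19; camera adjusted p = 2.1e-09, adjusted p = 0.31 with an estimated correlation). Sperm-specific ssp-10 had 2.77 ± 0.37 and ssp-19 had 2.48 ± 0.39.

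Germline and oocyte genes were also positive. Of the genes for germline proliferation, meiosis and P granules (the RNA granules of germ cells), 35 of 38 were called positive and none was called negative, with a median of 0.957 (SD 0.336; camera adjusted p = 1.3e-10, adjusted p = 0.45 with an estimated correlation). The RNA helicase gene glh-1 had 1.64 ± 0.39 and pgl-3, another P granule gene, had 1.64 ± 0.25. Of the oocyte and eggshell genes, 21 of 25 were called positive and 4 were not called, with a median of 0.91 (SD 0.459; camera adjusted p = 4.6e-06, adjusted p = 0.47 with an estimated correlation). The yolk receptor gene rme-2 had 1.35 ± 0.51 and mei-1, a subunit of the katanin of the meiotic spindle, had 1.33 ± 0.48. The preps differed in both groups: the median of the oocyte list was 0.384 on prep 3 and 1.41 on prep 4, and that of the major sperm proteins was 3.00 on prep 3 and 2.00 on prep 4.

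Genes for DNA replication and mitosis were called positive in 40 of 49 cases and negative in none, with a median of 0.796 (SD 0.331; camera adjusted p = 4.9e-09, adjusted p = 0.45 with an estimated correlation). The centromere gene hcp-4 had 1.39 ± 0.49 and the kinetochore gene knl-3 had 1.22 ± 0.13. Proteasome subunits were called positive in 28 of 31 cases, with a median of 0.641 (SD 0.141; camera adjusted p = 5.1e-08, adjusted p = 0.44 with an estimated correlation), led by pbs-6 at 0.91 ± 0.19 and rpn-5 at 0.86 ± 0.44. Cytosolic ribosomal proteins were called as a list with a median of 0.274 (SD 0.097; camera adjusted p = 0.0070, adjusted p = 0.47 with an estimated correlation), with 11 of 52 members called positive and 1 called negative, and 86.5% of the members had a positive mean. The paralogs rpl-11.1 at 1.39 ± 0.26 and rpl-11.2 at -0.64 ± 0.28 had opposite signs. Mitochondrial respiratory chain genes had a median of 0.234 (SD 0.09), with 7 of 34 positive and none negative (camera adjusted p = 0.041, adjusted p = 0.47 with an estimated correlation), among them the cytochrome c gene cyc-2.2 at 2.06 ± 0.65 and ucr-2.3 at 1.13 ± 0.24. That list lost its call when the arrays were centred on their medians (cameraPR adjusted p = 0.054) and with the title date as a block (adjusted p = 0.055). It also lost its call with array weights (adjusted p = 0.061) and without prep 3 (adjusted p = 0.096) or prep 4 (adjusted p = 0.072). Among all genes measured on every array 23.4% were called positive. Neither the ribosomal nor the respiratory chain list held a larger share of positive calls than that.

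Neuropeptide genes, which encode the peptide signals of neurons and some other cells, had the lowest median of the lists, -1.30 (SD 0.034), and 63 of 75 were called negative and 2 positive (camera adjusted p = 9.0e-20, adjusted p = 0.14 with an estimated correlation). The members nlp-12 and nlp-8 had -2.59 ± 0.43 and -2.58 ± 0.40. Of the neuronal synapse and transmitter genes, 34 of 44 were called negative and 1 was called positive, with a median of -0.78 (SD 0.211; camera adjusted p = 1.1e-11, adjusted p = 0.31 with an estimated correlation). The largest means were those of sbt-1, a chaperone of the neuropeptide-processing convertase, at -2.62 ± 0.10 and ida-1, a dense core vesicle gene, at -2.35 ± 0.21.

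Moulting genes, which act when larvae shed the cuticle, were called negative in 16 of 23 cases and positive in none, with a median of -0.895 (SD 0.182; camera adjusted p = 1.4e-07, adjusted p = 0.31 with an estimated correlation). The apical matrix genes noah-2 and noah-1 had -2.83 ± 0.38 and -2.69 ± 0.24. Hedgehog-related genes, many of them expressed in the epidermis, were called negative in 28 of 46 cases and positive in 2, with a median of -0.662 (SD 0.166; camera adjusted p = 2.3e-08, adjusted p = 0.31 with an estimated correlation), led by wrt-1 at -3.19 ± 0.42 and grl-20 at -3.16 ± 0.37. The 151 cuticle collagens went both ways, with 72 negative, 41 positive and 38 not called, and a median of -0.449 (SD 0.173; camera adjusted p = 0.0020, adjusted p = 0.45 with an estimated correlation). Nuclear hormone receptors were called negative in 67 of 235 cases and positive in 9, with a median of -0.172 (SD 0.06; camera adjusted p = 0.0021, adjusted p = 0.31 with an estimated correlation), and nhr-21 and nhr-57 had -2.41 ± 0.58 and -2.33 ± 0.26. The zygotic embryonic patterning genes had a median of -0.18 (SD 0.134), with 10 of 30 negative and 1 positive (camera adjusted p = 0.041, adjusted p = 0.31 with an estimated correlation). In that list sdz-24 had -1.25 ± 0.32 and the Hox gene ceh-13 had -1.06 ± 0.48. The call of the list was lost without prep 1 (cameraPR adjusted p = 0.083) and without prep 2 (adjusted p = 0.059).

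**Figure D2:**
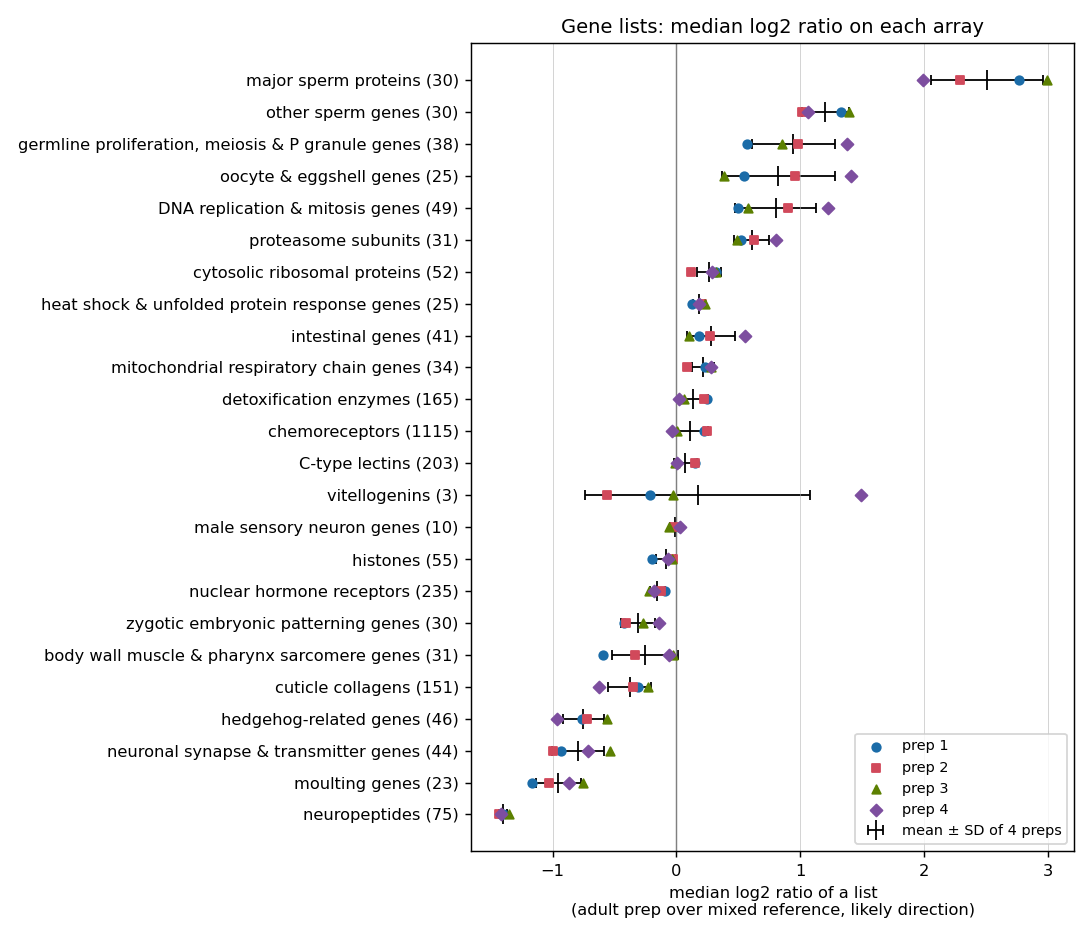
Median log2 ratio (horizontal axis, likely adult over reference) of the genes of each of the 24 lists on each array, with the number of genes tested in brackets. Symbols are single preps and bars are the mean ± SD of the 4 array medians; the major sperm proteins lie between 2.00 and 3.00 on the 4 arrays and the neuropeptides between -1.43 and -1.36.

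The remaining 9 lists were not called by camera. Of these, fry, which tests whether a list moves on balance one way and does not compare it with other genes, called the intestinal genes (adjusted p = 0.019), the histones (adjusted p = 0.034) and the male sensory neuron genes (adjusted p = 0.047). The vitellogenins, the yolk proteins made in the adult intestine, had values around 0 that differed between preps. On preps 1 to 4, vit-2 had -0.61, -0.75, -1.19 and 1.49, vit-5 had -0.21, -0.56, 0.30 and 0.58, and vit-6 had 0.15, 0.86, -0.03 and 2.53. The mean of vit-2 was -0.27 ± 1.20 (limma adjusted p = 0.60), that of vit-5 was 0.03 ± 0.51 (adjusted p = 0.93) and that of vit-6 was 0.88 ± 1.16 (adjusted p = 0.089). Without prep 4, vit-2 was called at -0.85 (adjusted p = 0.013), and without prep 1, vit-6 was called at 1.12 (adjusted p = 0.045), but without prep 4 vit-6 was at 0.33 (adjusted p = 0.26). The list's camera adjusted p was 0.80.

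Tissue markers were mixed. Of the body wall muscle and pharynx sarcomere genes 10 of 31 were called negative and 4 positive (camera adjusted p = 0.11), with the pharyngeal troponin C gene tnc-2 at -1.49 ± 0.44 and the pharyngeal myosin gene myo-1 at -1.01 ± 0.45. The mean of this list over genes with a value on every array used, -0.215, was -0.307 without prep 3, where the list was called (adjusted p = 0.040), and -0.098 without prep 1 (adjusted p = 0.43). Of the intestinal genes 15 of 41 were called positive and 5 negative (camera adjusted p = 0.11), with the lysozyme gene lys-3 at -3.35 ± 0.57 and the cathepsin B gene cpr-5 at 2.94 ± 0.50. Of the 10 male sensory neuron genes, a list meant as a check for males, none was called positive and 2 were called negative. These were cwp-4 at -0.87 ± 0.52 and cil-7 at -0.50 ± 0.28 (camera adjusted p = 0.38 for the list). Whether the mixed reference held males is not stated, so these ratios cannot show whether the preparations did. The call of cil-7 was lost without prep 1 (limma adjusted p = 0.080), prep 2 (adjusted p = 0.13) or prep 4 (adjusted p = 0.087), and that of rpl-11.2 without prep 2 (adjusted p = 0.052).

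Among the other lists, 42 of 55 histone genes were not called, 10 were called negative and 3 positive (camera adjusted p = 0.19), with the linker histone gene his-24 at -2.75 ± 0.42 and the histone variant gene his-71 at -1.56 ± 0.24. Heat shock and unfolded protein response genes were called positive in 8 and negative in 3 of 25 cases (camera adjusted p = 0.37), and hsp-12.3 had -2.21 ± 0.38. Of the 165 detoxification enzymes, 47 were called positive and 28 negative (camera adjusted p = 0.19). Of the 203 C-type lectins, 40 were called positive and 29 negative (camera adjusted p = 0.71), with clec-60 at -3.03 ± 0.23 and clec-52 at 2.42 ± 0.55. Of the 1115 genes taken by the symbol pattern for chemoreceptors, 978 were not called, 76 were called positive and 61 negative (camera adjusted p = 0.22). Among them, srb-13 had 2.57 ± 0.38 and srap-1 had -2.77 ± 0.97, although its symbol belongs to no receptor family. The mean of this list, taken in the same way, was 0.097 and became 0.155 without prep 4, where it was called (adjusted p = 0.046), and 0.049 without prep 2 (adjusted p = 0.58).

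Counted with p-values adjusted over the list alone, the germline, oocyte, both sperm and moulting lists kept the same counts. The ribosomal proteins went from 11 to 1 positive and from 1 to 0 negative, the respiratory chain genes from 7 to 4 positive, the chemoreceptors from 76 to 3 positive and from 61 to 17 negative, the nuclear hormone receptors from 9 to 7 positive and from 67 to 63 negative, and the male sensory neuron genes from 2 to 1 negative. The proteasome subunits went from 28 to 30 positive, the collagens from 41 to 45 positive and from 72 to 75 negative, and no other list changed by more than 4 genes.

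The third comparison asked whether the X chromosome, on which germline-expressed genes of this species are known to be sparse, differed from the autosomes. Positive calls were rarer on X: 210 of 2223 X-linked genes (9.4%) against 3242 of 12643 autosomal genes (25.6%), an odds ratio of 0.303 with a 95% interval from 0.26 to 0.351 (Fisher's exact test, two-sided, p = 6.1e-73). Negative calls were more frequent on X, with 695 genes (31.3%) against 2463 (19.5%), an odds ratio of 1.88 with a 95% interval from 1.70 to 2.08 (Fisher's exact test, p = 1.8e-33). Genes are not independent replicates, so these p-values describe this set of genes. The median log2 ratio of X-linked genes was -0.191 on prep 1, -0.209 on prep 2, -0.17 on prep 3 and -0.191 on prep 4. The medians over genes of the mean ratio of the 4 preps were -0.174 for X, 0.202 for chromosome I, 0.1 for II, 0.16 for III, 0.162 for IV and 0.041 for V. Chromosome V also had a low share of positive calls, 17% against 26.1% to 32.8% on the other autosomes.

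**Figure D3:**
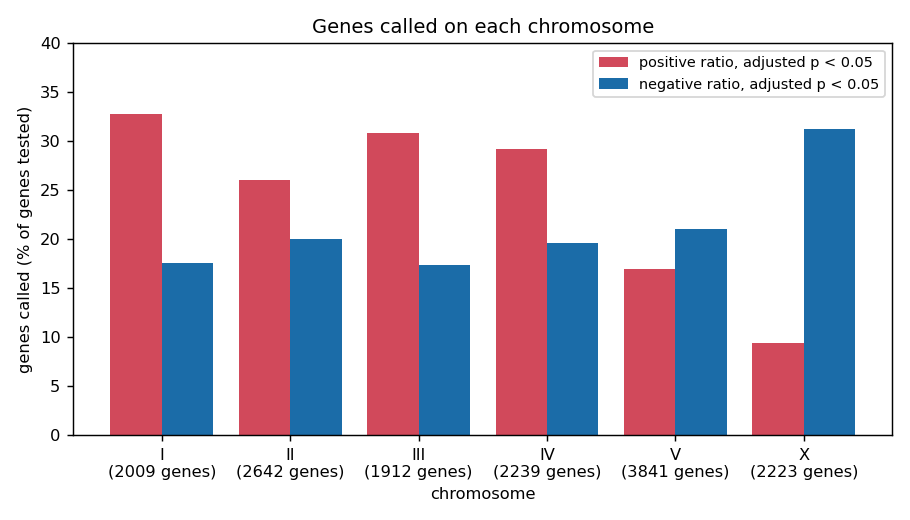
Share of the genes tested on each chromosome (vertical axis, percent) that limma called with a positive ratio (red) or a negative ratio (blue), with the number of genes under each chromosome. X has the smallest share of positive calls (9.4%) and the largest share of negative calls (31.3%).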

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

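Of 88 sets of 4 values tested for a single prep far from the others, 2 were flagged, fewer than the 4.4 that chance gives at 1 in 20. The male sensory neuron gene cwp-4 had a log2 ratio of -0.092 on prep 3 and lay between -1.19 and -1.03 on the other arrays. The median of the cytosolic ribosomal proteins was 0.118 on prep 2 and between 0.29 and 0.321 on the other arrays.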

How the results depend on the processing

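The count of called genes stayed within 1.5 times the 6639 reported under centring, scaling, both other minimum numbers of arrays, the robust prior, array weights and the title date as a block (6019), and it lay between 4954 and 5815 when 1 prep was left out. Adding a minimum size of log2 1 left 2132 genes, and a median of log2 1 in size with 1 sign on all arrays, in place of the test, gave 2082. The first takes a subset by construction, and 2081 of the 2082 were among the calls reported. In both sets 43.6% were positive, against 52.2% of the calls reported. Each probe tested by itself gave 8479 calls among 21497 probes. The majority of calls turned from positive (3468 against 3171) to negative with centring (3114 against 3405, 47.8% positive) and with scaling (3155 against 3420). The lists called numbered 14 or 15 under centring, scaling, the robust prior, array weights, the date block and without 1 prep, and 18 with fry, which added the intestinal, histone and male sensory neuron lists. With an estimated correlation the count was 0, in camera with 3 residual degrees of freedom, and 2 lists had an unadjusted p under 0.05. Apart from that setting, 8 of the changes in single lists were losses, all of the respiratory chain or embryonic patterning lists. The odds ratio of positive calls on X lay between 0.277 and 0.356 without 1 prep, and that of negative calls between 1.705 and 1.866, and no setting moved either past 1. Of 672 values of named genes under the alternatives, 655 kept direction and side of the threshold, 7 lost the call, 3 gained it and 7 changed sign. Most named genes were picked for large means in these same arrays, so this share says little about the stability of the 6639 calls. No value called in either setting changed sign. Those that did were vit-2, from -0.267 to 0.149 in preps 3 and 4 alone and 0.043 without prep 3 (-0.853 to 0.043 without 1 prep), and vit-5, from 0.026 to -0.021 with centring, -0.051 with array weights, -0.023 with the date block, -0.066 without prep 3 and -0.158 without prep 4 (-0.158 to 0.222 without 1 prep). The mean of vit-6, 0.879, lay between 0.33 and 1.181 without 1 prep. Among the lists, 4 means changed sign: heat shock genes to -0.003 with centring, C-type lectins to -0.013 and chemoreceptors to -0.045 in preps 3 and 4 alone, and vitellogenins from 0.213 to -0.227 without prep 4 (-0.227 to 0.386 without 1 prep). The cause was not tested. The fit of preps 3 and 4 alone gave every gene the same standard error of 0.262, so its calls leave out a gene's own spread and say nothing about stability. It called 4891 genes and 15 lists, among them vit-6 at 1.25 (adjusted p = 2.2e-05) from -0.03 and 2.53, and the intestinal list (adjusted p = 0.025). Those it did not call included cwp-4 (-0.562, adjusted p = 0.085), cil-7 (adjusted p = 0.37), rpl-11.2 (adjusted p = 0.25) and the embryonic patterning list (adjusted p = 0.25). The counts of values given here include that fit. The planned block fit with limma's own estimate of the correlation gave no value for 4 arrays in 3 blocks, and the correlation from differences took its place. With 1 group, the replicate numbers pair nothing. Turning the sign of arrays, a test chosen, like the date block, after seeing the data, gives 8 sets, too few for a share under 0.05: 1 set, the arrays as deposited, called 6639 genes, and the highest other count was 0. Signal over background is unknown, so weak spots could not be set apart.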

Other observations

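Gene families that share a symbol prefix give a view that lies partly beyond the fixed lists. The families counted next include some that share genes with those lists. Among these are msp, spe and ugt with positive calls, and flp, nlp, grl, dpy, col and nhr with negative calls. Of 99 families with at least 15 genes, 9 held more positive calls and 16 more negative calls than the rest of the 14639 genes measured on all arrays (one-sided Fisher's exact tests, adjusted over 198 tests). Positive calls were frequent among nuclear pore genes (npp, 15 of 21, adjusted p = 1.1e-04), translation initiation factors (eif, 11 of 19, adjusted p = 0.014), mitochondrial ribosomal proteins (mrpl, 12 of 25, adjusted p = 0.049, and mrps, 10 of 19, adjusted p = 0.045), the bath genes (18 of 31, adjusted p = 5.8e-04) and the glucuronosyltransferases (ugt, 25 of 62, adjusted p = 0.023). Negative calls were frequent among the insulin-like peptides (ins, 10 of 19, adjusted p = 0.026), the patched-related genes (ptr, 13 of 20, adjusted p = 5.8e-04), the transthyretin-related genes (ttr, 23 of 45, adjusted p = 2.1e-04), the globins (glb, 12 of 22, adjusted p = 0.0084) and the pals genes (13 of 23, adjusted p = 0.0033). Genes of a family are similar in sequence and often neighbours, so these tests count genes and not independent events. Among 5056 probes that have no single gene name, 691 were called positive and 919 negative.

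The patterns below were noticed in the data first. The tests of adult age, of a single array, of signal strength and of the cyp-35 genes were chosen after their results were seen, as were those of the symbol families.

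The major sperm proteins and the oocyte genes ordered the preps in opposite ways. The median of the major sperm proteins was 3.00 on prep 3, 2.77 on prep 1, 2.29 on prep 2 and 2.00 on prep 4, while that of the oocyte and eggshell genes was 0.384, 0.545, 0.956 and 1.41 on the same arrays. The other sperm genes, at 1.331, 1.019, 1.399 and 1.063 on preps 1 to 4, did not follow the reverse of the oocyte order. A different spread of ratios between arrays as the whole cause is argued against: centring and scaling moved the median over genes of the gap between preps 3 and 4 for the oocyte genes (prep 4 minus prep 3) from 0.906 to 0.636 (95% bootstrap interval 0.501 to 0.9, above 0 in 24 of 25 genes). Scaling raised that of the major sperm proteins (prep 3 minus prep 4) from 1.002 to 1.798 (1.612 to 1.928, 30 of 30 genes) and of the other sperm genes from 0.442 to 0.913 (0.384 to 1.309, 27 of 30 genes). These intervals are over correlated genes (estimated correlation 0.68 in the oocyte list) on 2 single arrays. Preps 3 and 4 share a date in the titles, so that date does not separate them. A candidate explanation is that the preps differed in adult age, because sperm are made before oocytes in hermaphrodites and yolk genes are active in adults, but the vitellogenins do not decide it. Prep 4 was the highest array for 3 of 3, while prep 3 was the lowest for 2 of 3: vit-5 had -0.21, -0.56, 0.30 and 0.58 on preps 1 to 4. These genes are similar in sequence and so not independent, and adult age remains open.

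The shortage of positive ratios on the X chromosome was also present among genes outside the lists. Without every gene of the 24 lists, 191 of 2048 X-linked genes and 2819 of 10293 autosomal genes had positive calls, an odds ratio of 0.273 with a 95% interval from 0.232 to 0.319 (Fisher's exact test, p = 3.6e-79). Of the 3242 autosomal genes with positive calls, 2819 lay outside the lists, so taking the lists out could change the comparison little. Any germline genes outside the lists stayed in, so this removal does not test germline expression as a cause. A single array is argued against, because X had the lowest median of the 6 chromosomes on 4 of 4 arrays. Weaker signal of X-linked spots, which would draw ratios towards 0 and make negative calls rarer too, is argued against as the whole cause by the odds ratio of 1.88 for negative calls (95% interval 1.70 to 2.08). A larger share of germline RNA in the adults than in the reference remains open and would be consistent with the positive germline lists, but was not tested apart from them.

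The cyp-35 genes, a cytochrome P450 family known to respond to foreign compounds, differed between preps, and were singled out for that. Their median was 2.72 on prep 1 and 2.78 on prep 2 but 0.471 on prep 3 and 0.573 on prep 4, and cyp-35A3 had 7.04, 3.78, 1.13 and 0.78 on preps 1 to 4. The median difference of the 9 genes between preps 1 and 2 and preps 3 and 4 was 1.959, and that of the 153 other detoxification enzymes was 0.173. For 8 of 9 genes both of preps 1 and 2 lay above both of preps 3 and 4. A split between these pairs of preps was not particular to this family. On preps 1 to 4 the chemoreceptor list had medians of 0.221, 0.244, 0.001 and -0.039. The C-type lectins had 0.154, 0.153, -0.015 and 0.001. The body wall muscle and pharynx list split the other way, at -0.593, -0.335, -0.029 and -0.057. Preps 3 and 4 share a date in the titles, and preps 1 and 2 are dated to consecutive days of the next month. A batch of cultures and a batch of hybridisations therefore cannot be told apart, and signal shared between the similar cyp-35 genes was not tested.

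In 40 genes 1 array alone lay more than 3 log2 units from the gene's median, 22 of them on prep 1, 13 on prep 2, 1 on prep 3 and 4 on prep 4, and gadr-6 had 8.95 on prep 2 against values from -0.38 to 0.05 on the other arrays.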
